A study of Arabidopsis thaliana and Serendipita indica and Serendipita vermifera with 30 samples.

How the data were processed

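The series holds 30 samples of total RNA, labelled with Cy3 and hybridised to 2 Agilent one-colour array designs of 15 arrays each. Per the labels, Arabidopsis Col-0 plants were grown for 14 days and then inoculated with P. indica spores or S. vermifera mycelium, or mock treated. Roots of 45 to 60 plants, or of 80 to 100 plants for P. indica at 3 and 14 dpi, were pooled per sample in 3 independent biological repetitions. For the P. indica samples of 3 and 14 dpi the time label conflicts with the sample titles, and the titles were used. The P. indica design has 27385 Arabidopsis and 12636 fungal probes, the S. vermifera design 27385 and 15146, plus 472 probes named by a genome position, which were not tested. The fungal probes came without product names, so 16 fungal lists defined by keywords were not used here.

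Per the file headers, the scans were extracted with Agilent Feature Extraction 10.7.3.1, while the submitters' processing notes name version 10.5. The deposited scanner files give, per spot, an intensity that is background-subtracted and spatially detrended (the processed signal) and raw median intensities of spot and local background, with no normalization between arrays. The deposited series matrix gives log2 values, which by their distribution were quantile-normalized between arrays within the probes of an organism, and it leaves out the P. indica probes. In the 3 mock files of 7 dpi the processed signal of Arabidopsis probes did not follow the background-subtracted signal of the same file and held 1 value for all spots of a probe. The series matrix holds the same values, and which scan they come from is not stated. They correlated at 0.938 to 0.939 with their own scan. With the mock arrays of 3 and 14 dpi on the other design they correlated at 0.976 to 0.990. At both times each correlated most with the mock array of its own replicate number (0.984 to 0.990). These values go with a source in other scans, which stays open. If so, S. vermifera against mock sets the roots against controls from another design, and perhaps from another time. The processed signal of P. indica 7 dpi replicate 1 also departed from its own scan (correlation 0.606 over 4299 plant and 0.839 over 1057 fungal probes well above background), without repeated values, and this array was kept. The processed signal was kept as planned, and a second fit from the background-subtracted signal was added after this was seen.

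All values were computed with R 4.3.3, limma 3.58.1 and the data.table package (version 1.17.8). Which groups, contrasts, gene lists, filters and alternatives to use was fixed before the data were examined, apart from the additions named as such. The log2 processed signal was scaled per array by subtracting the 75th percentile over the probes of the organism tested, because the share of fungal RNA differs between samples. Where under 50% of these probes were well above background on any array of a fit, the percentile was taken over probes well above background on every array. Spots with outlier flags were left out, spots of a probe and probes of a gene were averaged, and a probe was kept if it was well above background on all arrays of at least 1 group. Probes lit by the other organism were left out: 733 P. indica and 127 S. vermifera probes lit by mock roots on at least 2 of every 3 arrays, and 391 Arabidopsis probes lit by S. vermifera alone. Arabidopsis probes that P. indica RNA might light could not be found, since no P. indica culture was arrayed. Replicates 1 and 2 of the S. vermifera roots at 7 dpi differed by no more than spots of 1 array do (variance ratio 0.690), and were averaged and counted as 1 sample. Depth is given as the share of probes well above background.

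Each contrast was tested with limma (lmFit and eBayes, two-sided) with Benjamini-Hochberg adjustment over all genes of the contrast, and a gene was called at an adjusted p under 0.05 with a fold of at least 2. Tests of S. vermifera genes covered roots at 3, 7 and 14 dpi against the fungus alone and against each other. P. indica genes were tested between times in roots. Arabidopsis genes were tested with P. indica against mock at 3 and 14 dpi, for the difference of these effects, for mock roots of 14 against 3 dpi, and with S. vermifera against mock at 7 dpi. Where a called gene was below background in 1 group, "at least" folds were computed against the lowest signal well above background on each array of that group. The 16 Arabidopsis lists cover indole glucosinolates and camalexin, ER body and PYK10, pattern-triggered immunity, salicylic acid, jasmonate and ethylene, phosphate starvation, nitrogen, iron and coumarins, hypoxia, sugar transport, endodermis and suberin, root hair, cell division, heat shock, senescence, and shoot photosynthesis as a marker of another tissue. Lists were tested with camera at a preset correlation of 0.01, adjusted over the 16 lists, and their counts are given over all genes and adjusted over the list alone. With an estimated correlation no list of these contrasts was called from the processed signal. Fungal relative to plant signal was compared by exact permutation tests, and overlaps are given beside the number that independent lists would share.

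Named genes followed a rule fixed in advance: per contrast the 10 largest rises and 10 largest falls among called genes with a name and without overlap of arrays, up to 4 members of each list with the smallest p, and 7 P. indica genes known from earlier work. Fungal genes without names were limited to 2 identifiers per direction. The text names part of these. Genes of which the reference and the lists gave different symbols were left out of the text.

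The alternatives were a normexp background correction (offset 50, on median instead of mean spot intensities, which the files lack), the percentile over the other probe set or over all organisms, quantile normalization, the series matrix values, no filter and a stricter filter on dim probes, keeping cross-lit probes, the brightest probe of a gene, only the compared groups, eBayes with trend and robust settings, no fold minimum, replicate and slide blocks, leaving out each array, and for lists an estimated correlation and fry. Added after the data were seen were the background-subtracted signal, the 7 dpi arrays as separate samples (alone and with blocks), leaving out P. indica 7 dpi replicate 1 from contrasts of other groups, alone and with the slide block, and the slide block for lists. In simulated data for the 14 contrasts, recovery was counted by adjusted p alone. Of genes changed 2-fold, 73.1% (difference of effects) to 95.2% (P. indica against mock at 3 dpi) were recovered. By that rule the fits made 4 to 16 false calls, and with the fold minimum 0 to 5. Recovery with the fold minimum was not counted. It would be lower for genes changed 2-fold, whose median fitted size was 0.97 to 1.03 on the log2 scale.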

Results

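Gene expression was measured on 30 one-colour Agilent arrays that carry probes for Arabidopsis thaliana and for 1 of 2 root-colonising fungi of the order Sebacinales, Piriformospora indica or Sebacina vermifera. The samples form 10 groups of 3: roots at 3, 7 and 14 days post inoculation (dpi) with each fungus, mock-treated roots at 3, 7 and 14 dpi, and S. vermifera grown without a plant for 3 days. Each array design held 15 arrays. The P. indica design carried the 9 P. indica root arrays and the mock roots of 3 and 14 dpi, and the S. vermifera design carried the 9 S. vermifera root arrays, the fungus alone and the mock roots of 7 dpi. Arabidopsis was represented by 27257 genes on both designs, P. indica by 11741 and S. vermifera by 15146. With 1 exception, 71.5% to 76.7% of the Arabidopsis probes were well above background in root samples, and 43.8% to 75.8% of the fungal probes in inoculated roots. The exception was replicate 1 of the P. indica roots at 7 dpi, with 15.7% of plant and 8.37% of fungal probes well above background and a mean negative-control signal of 2386, against 40.7 to 73.5 on the other arrays of that design. Its processed signal correlated at 0.606 over plant probes and 0.839 over fungal probes with the background-subtracted signal of its own scan. The number of arrays per group limits the precision of every value. Fold changes are given as log2 values with the standard error (SE) of the limma fit. A gene is said to have risen or fallen where the adjusted p was below 0.05 and the fold at least 2. Apart from PIIN_02121 at 14 against 3 dpi, no gene named as changed in a group comparison had overlapping array values between its groups. The largest rises and falls were chosen for this separation, so it is no further evidence for them. Chance gives it to 10% of genes with 3 against 3 arrays. With P. indica against mock at 3 dpi 12284 of 20728 tested genes had it.

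How much fungal RNA each root sample held, relative to plant RNA, was compared through the median fungal minus the median plant signal of each array. In P. indica roots this difference was -4.38 ± 0.37 (log2, SD, n = 3) at 3 dpi, -2.81 ± 0.27 at 7 dpi and -1.70 ± 0.55 at 14 dpi. In S. vermifera roots it was -2.50 ± 0.33 at 3 dpi, -3.56 ± 0.17 at 7 dpi (n = 2 after 2 near-identical arrays were averaged) and -2.64 ± 0.09 at 14 dpi. Mock roots had -6.78 ± 0.47 at 3 dpi, -6.95 ± 0.36 at 7 dpi and -6.31 ± 0.38 at 14 dpi, which is the background of this measure. Each inoculated group lay above the mock arrays of its design, and P. indica roots lay above those of the time before, in all cases without overlap. P. indica roots of 7 dpi were not tested against mock roots. Each of the other comparisons gave a two-sided exact permutation p of 0.1 (Benjamini-Hochberg 0.11 over 11 comparisons). That is the smallest that 3 against 3 or 2 against 3 arrays allow, so none can pass 0.05. With the background-subtracted plant signal of each scan the P. indica differences were 2.53 at 7 against 3 dpi (1.57 with the processed signal) and 0.14 at 14 against 7 dpi (1.11). There replicate 1 of 7 dpi went from -2.93 to -0.03, above all P. indica arrays of 14 dpi. Without that replicate these differences were 1.63 and 1.04, so the size of the step from 7 to 14 dpi depends on it. For S. vermifera at 14 against 3 dpi the exact permutation p was 0.4 and the difference, -0.14, was smaller than the spread between replicates. Against the 7 dpi mock roots the differences were 4.45, 3.39 and 4.31 at 3, 7 and 14 dpi, and 3.17, 2.11 and 3.04 with the background-subtracted plant signal of each scan.

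**Figure D1:**
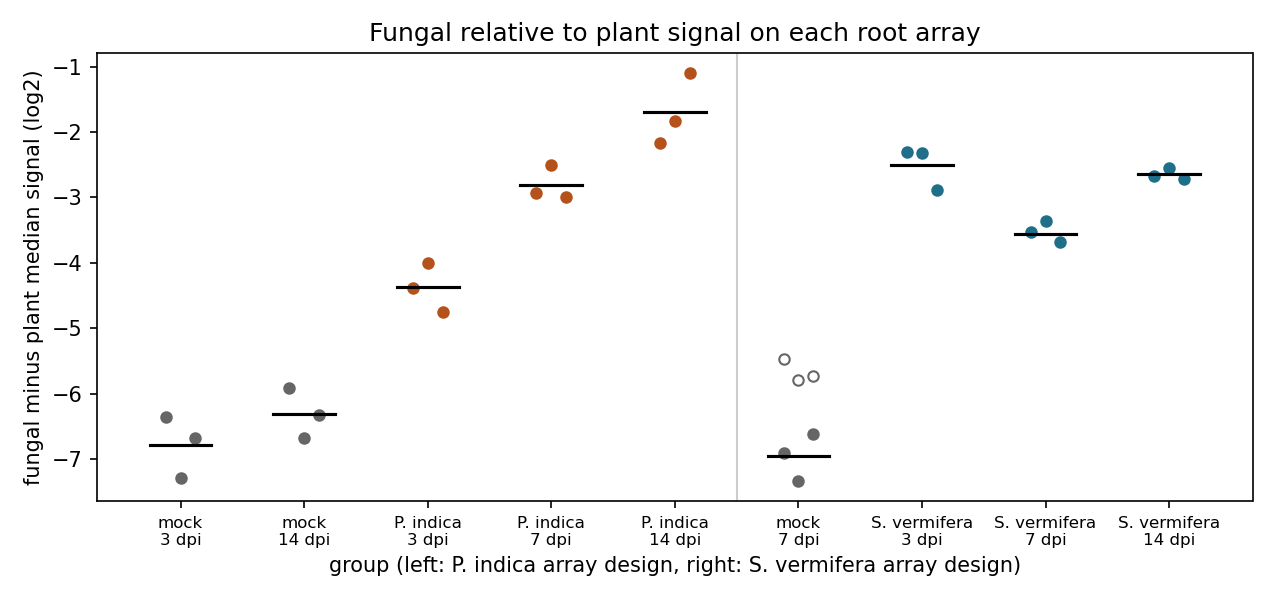
Median fungal minus median plant signal (log2, vertical axis) of each root array by group (horizontal axis), with the P. indica array design on the left and the S. vermifera design on the right. Filled points are arrays, lines are group means (the 2 averaged S. vermifera arrays at 7 dpi counted once), and open points show the 7 dpi mock arrays computed from the background-subtracted signal of their own scan; P. indica means went from -4.38 at 3 dpi to -1.70 at 14 dpi.

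The comparison of S. vermifera in roots with S. vermifera alone asks which fungal genes differ in the plant. The fungus alone was arrayed at 3 days only. At 7 and 14 dpi the time of growth therefore differs as well and cannot be told apart from growth in the plant. Sebve1_03508 was below background in the fungus alone and was at least 24.2-fold higher in roots at 3 dpi, at least 49.9-fold at 7 dpi and at least 16.4-fold at 14 dpi. Sebve1_12373 rose by 5.74 (SE 0.15, adjusted p = 9.5e-08) at 3 dpi and by 6.34 (SE 0.17) at 7 dpi. Sebve1_10002 fell by 4.53 (SE 0.20, adjusted p = 2e-06) at 3 dpi, and Sebve1_11499 fell by 4.36 (SE 0.56, adjusted p = 0.00034) at 7 dpi. Of 11341 S. vermifera genes tested, 1542 differed from the fungus alone at 3 dpi (518 higher, 1024 lower), 1552 at 7 dpi (610 higher, 942 lower) and 1504 at 14 dpi (519 higher, 985 lower). At all 3 times 214 of these genes were higher and 304 lower, against 1.27 and 7.39 from independent lists of these sizes. The 3 lists share the fungus-alone arrays, which can raise the overlap by an amount that was not tested. In 20 simulations without change no gene was in all 3. Few genes are called where nothing changes, so these simulations cannot size that amount. Which direction prevails depends on the background correction and the filter on dim probes. The strict filter gave 469 higher and 437 lower, 354 and 281, and 418 and 297 at 3, 7 and 14 dpi, and no dim filter 2604 and 1034, 3840 and 948, and 3072 and 988. With a normexp correction the counts were 1967 higher and 217 lower at 3 dpi, 5227 and 165 at 7 dpi, and 2751 and 190 at 14 dpi.

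Between times in roots, 741 S. vermifera genes differed at 7 against 3 dpi (533 higher, 208 lower), 706 at 14 against 3 dpi (405 higher, 301 lower) and 794 at 14 against 7 dpi (368 higher, 426 lower). The excess of higher genes at 7 dpi did not hold across scalings. A normexp correction widened it, with 2893 higher and 21 lower at 7 against 3 dpi and 62 and 1396 at 14 against 7 dpi, and the percentile over all organisms gave 22 and 4331, and 2941 and 30. Quantile normalization gave 198 higher and 545 lower at 7 against 3 dpi, the deposited series matrix values 193 and 692, and a fit of the compared groups alone 84 and 168. Without replicate 3 of the 7 dpi roots 395 genes differed, but 1 averaged sample then stands for 7 dpi, and the spread comes from the other groups alone.

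For P. indica no culture without a plant was arrayed, so its genes were compared between times in roots. PIIN_06951 was below background at 3 dpi and at least 16.6-fold higher at 7 dpi and 30.2-fold higher at 14 dpi. PIIN_05934 fell by 5.98 (SE 0.24, adjusted p = 2.8e-07) from 3 to 14 dpi. Of 7 P. indica genes chosen before the data were examined, 6 were measured. PIIN_02121 rose by 4.46 (SE 0.69, adjusted p = 0.00093) from 3 to 7 dpi, to -0.81, and was at -3.14 ± 1.34 (SD) at 14 dpi. Its change was 2.13 (adjusted p = 0.026) from 3 to 14 dpi, with overlapping arrays, and -2.33 (adjusted p = 0.036) from 7 to 14 dpi. The former call ended without replicate 1 or 3 of 3 dpi or 1 or 2 of 14 dpi (adjusted p = 0.05 to 0.1), the latter without replicate 1 or 2 of 7 dpi or 1 or 3 of 14 dpi (0.07 to 0.11). PIIN_03211 rose by 2.75 (SE 0.61, adjusted p = 0.0062) from 3 to 7 dpi and by 5.13 (SE 0.61, adjusted p = 0.00013) from 3 to 14 dpi. PIIN_02023 rose by 1.14 from 3 to 7 dpi (0.96, under the fold minimum, without replicate 2 of 7 dpi) and by 1.56 from 3 to 14 dpi, and PIIN_05825 rose by 1.3 from 3 to 7 dpi. After a normexp correction these were at 0.03, 0.24 and 0.61 and no longer passed. PIIN_01005 was at -1.13 from 7 to 14 dpi (adjusted p = 0.035), a call that ended without any of 4 arrays, replicates 1 and 2 of 7 dpi and 2 and 3 of 14 dpi (adjusted p = 0.069 to 0.091). PIIN_08944 missed the fold minimum from 3 to 7 dpi, at -0.89, and passed it without replicate 3 of 3 dpi, at -1.15. Of 8035 P. indica genes tested, 1026 differed at 7 against 3 dpi (581 higher, 445 lower), 1624 at 14 against 3 dpi (1226 higher, 398 lower) and 489 at 14 against 7 dpi (416 higher, 73 lower). The median of all genes was 0.24 at 14 against 3 dpi and 0.22 at 14 against 7 dpi, and the counts include that shift. The percentile used for scaling rested on 669 of 12636 fungal probes, those well above background on every array of the fit. Over all P. indica probes the medians were 0.1 and 0.01, and with quantile normalization 0.1 and 0. The shift thus depends on the scaling. A normexp correction gave 142 higher and 2020 lower at 7 against 3 dpi, 263 and 1856 at 14 against 3 dpi, and 133 and 55 at 14 against 7 dpi. With no dim filter the lower genes prevailed at each, with 564 higher and 2944 lower, 1192 and 2897, and 458 and 1451. Without replicate 1 of the 7 dpi roots, whose background stood apart, 217 genes differed at 14 against 7 dpi.

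Arabidopsis roots at 3 dpi with P. indica were compared with mock roots of the same age to find the plant genes that respond early. The 4 largest rises among genes with a name were in cytochrome P450 genes. CYP82C2 (AT4G31970), which hydroxylates indole carbonyl nitriles, rose by 7.85 (SE 0.50, adjusted p = 1.8e-06). CYP71A12 (AT2G30750), which acts on indole-3-acetaldoxime, rose by 7.79 (SE 0.27, adjusted p = 1.4e-08). CYP82C4 (AT4G31940), which makes the coumarin sideretin, rose by 7.76 and its neighbour CYP82C3 (AT4G31950) by 7.73; genes of near-identical families may share probe signal. GLIP1 (AT5G40990), a secreted lipase, rose by 6.08, NAC042 (AT2G43000), a transcription factor of camalexin synthesis, by 4.11, and the lipase PLA2A (AT2G26560) by 4.01. Of 20728 genes tested, 1288 differed (801 higher, 487 lower).

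By the gene lists fixed before the data were examined, 11 of 20 indole glucosinolate and camalexin genes rose and none fell (11 adjusted over the list alone), with CYP81F2, which modifies indole glucosinolates, up by 4.19. The list's camera adjusted p was 4.37e-09, and the adjusted p = 0.46 with an estimated correlation. Of 20 pattern-triggered immunity genes 6 rose, WRKY33 among them by 1.57, and 1 fell (6 and 1 adjusted over the list alone; adjusted p = 0.00019, and adjusted p = 0.46 with an estimated correlation). The gene that fell was FLS2, the flagellin receptor, at -1.47. Of 14 nitrogen uptake and assimilation genes 1 passed, the nitrate transporter gene NRT2.1 at 1.32, while the nitrate reductase genes NIA1 and NIA2 were at 0.79 each (1 adjusted over the list alone; adjusted p = 0.0283, and adjusted p = 0.46 with an estimated correlation). No cell division gene passed the fold minimum, and the list was lower as a set with CYCA1;1 and CYCB1;1 at -0.71 each (0 adjusted over the list alone; adjusted p = 0.00878, and adjusted p = 0.46 with an estimated correlation).

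The other 12 lists were not called at 3 dpi. Of 13 salicylic acid genes 4 rose (4 adjusted over the list alone; adjusted p = 0.125), including CBP60G by 2.66 and SARD1 by 2.30, transcription factors of salicylic acid synthesis, and the glutaredoxin gene GRX480 by 1.24. Of 16 iron deficiency and coumarin genes 4 rose, with the transporter gene OPT3 up by 1.62, and 1 fell (4 and 1 adjusted over the list alone; adjusted p = 0.161). Of 14 jasmonate and ethylene genes 1 rose and 1 fell (1 and 1 adjusted over the list alone; adjusted p = 0.685), the latter VSP2, a vegetative storage protein, at -1.69. Of 4 senescence genes 1 fell (1 adjusted over the list alone; adjusted p = 0.88). No member passed in the lists of ER body and PYK10 (adjusted p = 0.27; PYK10 itself 0.51), phosphate starvation (0.201), hypoxia (0.362), sugar transport (0.88), endodermis and suberin (0.594), root hair (0.789), heat shock (0.88) and shoot photosynthesis (0.125), and the counts adjusted over the list alone were also 0. Among the genes with the largest falls were the amino acid transporter gene UMAMIT14 at -3.27, BNQ3 at -2.80, the arabinogalactan protein gene AGP30 at -2.43, HSD4 at -2.35 and the lipid transfer protein gene DIR1 at -2.29.

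All mock arrays of this design lay on 1 slide and all P. indica arrays of 3 and 14 dpi on the other. The 7 dpi P. indica arrays lay on both. Per the file headers the slides were extracted with different protocols, so slide and protocol cannot be told apart here. Among the 7 dpi P. indica arrays, replicate 3, on the slide of the mock arrays, differed 2-fold from replicate 2 in 777 genes. It differed from replicate 1 in 126 genes, and replicates 1 and 2, both on the other slide, differed in 142. The size of the slide difference thus depends on replicate 1. With the slide as a block, estimated from these 7 dpi arrays, 257 genes differed at 3 dpi (213 higher, 44 lower). CYP82C2, CYP71A12, CYP82C4, CYP82C3, GLIP1, CYP81F2, NAC042, PLA2A and GRX480 passed with it. Without replicate 1 of 7 dpi the block gave 38 genes (27 higher, 11 lower), and of those 9 genes CYP82C2, CYP71A12, CYP82C3 and PLA2A passed, while CYP82C4 (adjusted p = 0.06), GLIP1, CYP81F2, NAC042 and GRX480 did not. WRKY33, FLS2, CBP60G, SARD1, VSP2, NRT2.1, OPT3, UMAMIT14, BNQ3, AGP30, HSD4 and DIR1 did not, nor did the nitrogen list (adjusted p = 0.0977). Over all genes called at 3 dpi the median went from 1.45 to 1.25 for higher and from -1.32 to -1.09 for lower genes. The SE went from 0.20 to 0.37 for WRKY33 and from 0.31 to 0.56 for CBP60G, whose changes were 1.36 and 2.38 with the block. NRT2.1 and OPT3 came under the fold minimum, at 0.76 and 0.94. BNQ3 went from -2.80 to -1.93, SARD1 from 2.30 to 1.63, HSD4 from -2.35 to -1.78 and AGP30 from -2.43 to -1.96. FLS2, VSP2 and DIR1 grew in size, to -1.55, -1.87 and -2.47. A loss with this block can thus come from a wider error, a smaller change or both, and shows no slide effect by itself. FLS2 also missed the fold minimum after a normexp correction, at -0.87. Each P. indica sample of 3 and 14 dpi pooled 80 to 100 plants and each mock sample 45 to 60, per the labels.

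**Figure D2:**
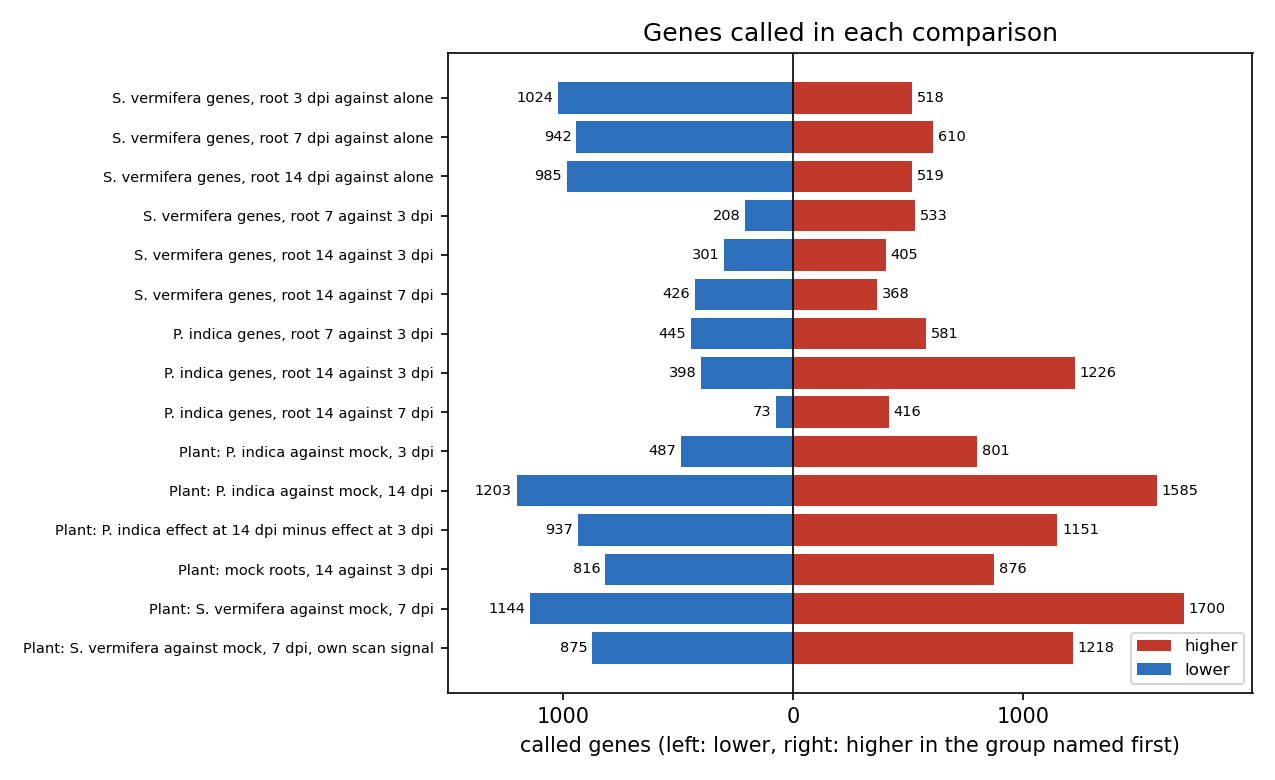
Number of genes called in each comparison (horizontal axis), lower to the left and higher to the right, with comparisons on the vertical axis; the last bar repeats S. vermifera against mock from the background-subtracted signal of each scan. P. indica against mock roots gave 1288 genes at 3 dpi and 2788 at 14 dpi, and the split by direction moved with the background correction, the scaling and the filter on dim probes.

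At 14 dpi the same P450 genes stood far above mock roots. In mock roots of 14 dpi CYP82C2, CYP71A12 and CYP82C3 were below background, and with P. indica they were at least 815-fold, 368-fold and 284-fold higher. CYP82C4 rose by 10.64 (SE 0.58, adjusted p = 2.4e-08), NAC042 by 6.43 and GLIP1 by 6.26, and the dirigent protein gene DIR5 (AT1G64160) was at least 36.8-fold higher. Among the largest falls were AZI1 (AT4G12470) at -6.31 (SE 0.40, adjusted p = 7.4e-08) and EARLI1 (AT4G12480) at -5.85, neighbouring genes of lipid transfer proteins. The small heat shock gene HSP23.6-MITO (AT4G25200) was at -5.80, the immunophilin gene ROF2 (AT5G48570) at -4.96 and TIN1 (AT5G64510) at -4.35. SRO4 was at least 26.2-fold lower, and GA20OX2, of gibberellin synthesis, at least 6.20-fold lower. Of 20728 genes 2788 differed (1585 higher, 1203 lower), and 2658 with the slide as a block (2808 without replicate 1 of 7 dpi). The lower genes prevailed with the percentile over all organisms (912 higher, 3168 lower) and with no dim filter (1661 and 1873).

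Defence lists were higher with P. indica than in mock roots at 14 dpi. Of 20 indole glucosinolate and camalexin genes 13 rose and none fell (13 adjusted over the list alone; adjusted p = 7.57e-09, and adjusted p = 0.176 with an estimated correlation), with CYP81F2 up by 5.70. Of 6 ER body and PYK10 genes 2 rose (2 adjusted over the list alone; adjusted p = 0.00228, and adjusted p = 0.105 with an estimated correlation), the beta-glucosidase gene BGLU22 by 2.48 and PBP1 by 1.61, while PYK10 was at 0.81. Relative to mock roots of 3 dpi the ER body median was -0.64 in mock roots of 14 dpi, and 0.43 and 0.41 in P. indica roots of 3 and 14 dpi. With the slide as a block and without replicate 1 of 7 dpi PBP1 missed the fold minimum, at 0.84. Of 20 pattern-triggered immunity genes 9 rose (9 adjusted over the list alone; adjusted p = 0.000274, and adjusted p = 0.239 with an estimated correlation), with the danger peptide precursor PROPEP3 up by 3.60 and the peroxidase PER4 by 3.45. Of 13 salicylic acid genes 8 rose (8 adjusted over the list alone; adjusted p = 0.000183, and adjusted p = 0.176 with an estimated correlation), with CBP60G up by 5.49, FMO1 by 3.45 and GRX480 by 2.21, and PBS3 at least 14.7-fold higher. Of 14 jasmonate and ethylene genes 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.0442, and adjusted p = 0.325 with an estimated correlation). JAZ1 rose by 1.78, JAZ5 and the chitinase gene PR3 by 1.51 each, and VSP2 fell by 2.69, where mock roots had risen by 2.73 since 3 dpi (levels of -3.38 and -0.64 in mock roots of 3 and 14 dpi, and -3.33 in P. indica roots of 14 dpi). The call of the list was lost with the slide as a block (adjusted p = 0.131).

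Among the other lists at 14 dpi, 7 of 16 iron deficiency and coumarin genes rose (7 adjusted over the list alone; adjusted p = 0.00337, and adjusted p = 0.176 with an estimated correlation), CYP82C4 the most. Of 7 sugar transport genes 1 rose, SWEET2 by 2.35 (1 adjusted over the list alone; adjusted p = 0.0338, and adjusted p = 0.239 with an estimated correlation). The sugar transport median relative to mock roots of 3 dpi was -0.59 in mock roots and -0.03 in P. indica roots of 14 dpi. Of 10 hypoxia genes 9 fell (9 adjusted over the list alone; median -2.25, adjusted p = 1.67e-05, and adjusted p = 0.202 with an estimated correlation), including ADH1 at -3.54, PCO2 at -3.38 and LBD41 at -2.07. Of 9 heat shock genes 9 fell (9 adjusted over the list alone; median -2.82, adjusted p = 2.83e-05, and adjusted p = 0.202 with an estimated correlation), with HSP90.1 at -3.42. Of 12 shoot photosynthesis genes 5 fell (5 adjusted over the list alone; adjusted p = 0.0466, and adjusted p = 0.647 with an estimated correlation), LHCB1.1 at -2.60 and LHCA1 at -2.63. That call was also lost with quantile normalization (adjusted p = 0.0562) and with a replicate block (adjusted p = 0.0603). The hypoxia, heat shock and photosynthesis lists were called higher in mock roots of 14 than of 3 dpi (adjusted p = 0.164, 0.381 and 0.596 with an estimated correlation). Relative to mock roots of 3 dpi, the hypoxia median was 3.71 in mock roots of 14 dpi and 1.35 in P. indica roots of 14 dpi, and the heat shock medians were 2.95 and -0.53.

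The lists that were not called at 14 dpi were phosphate starvation (2 rose, 4 fell of 17; adjusted p = 0.158), nitrogen (1 rose, 1 fell of 14; adjusted p = 0.422), root hair (1 fell of 7, the expansin gene EXPA7 at -1.33; adjusted p = 0.367), senescence (2 rose of 4; adjusted p = 0.555), endodermis and suberin (0 of 12; adjusted p = 0.0755) and cell division (0 of 7; adjusted p = 0.528). Their counts adjusted over the list alone were the same. In the phosphate list SPX3 rose by 2.41, and the acid phosphatase gene PAP17 and the transporter gene PHT1;4 fell, at -1.59 and -1.11. PHT1;4 missed the fold minimum with the slide as a block and without replicate 1 of 7 dpi, at -0.96. The asparagine synthetase gene ASN1 was at 2.01 and SEN1 at 2.28, calls that were lost with the slide as a block (adjusted p = 0.061 and 0.077), and SAG13 rose by 5.42. SEN1 had a level of -2.92 in mock roots of 3 dpi, -7.99 in those of 14 dpi and -5.71 in P. indica roots of 14 dpi, so mock roots changed more than the contrast.

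**Figure D3:**
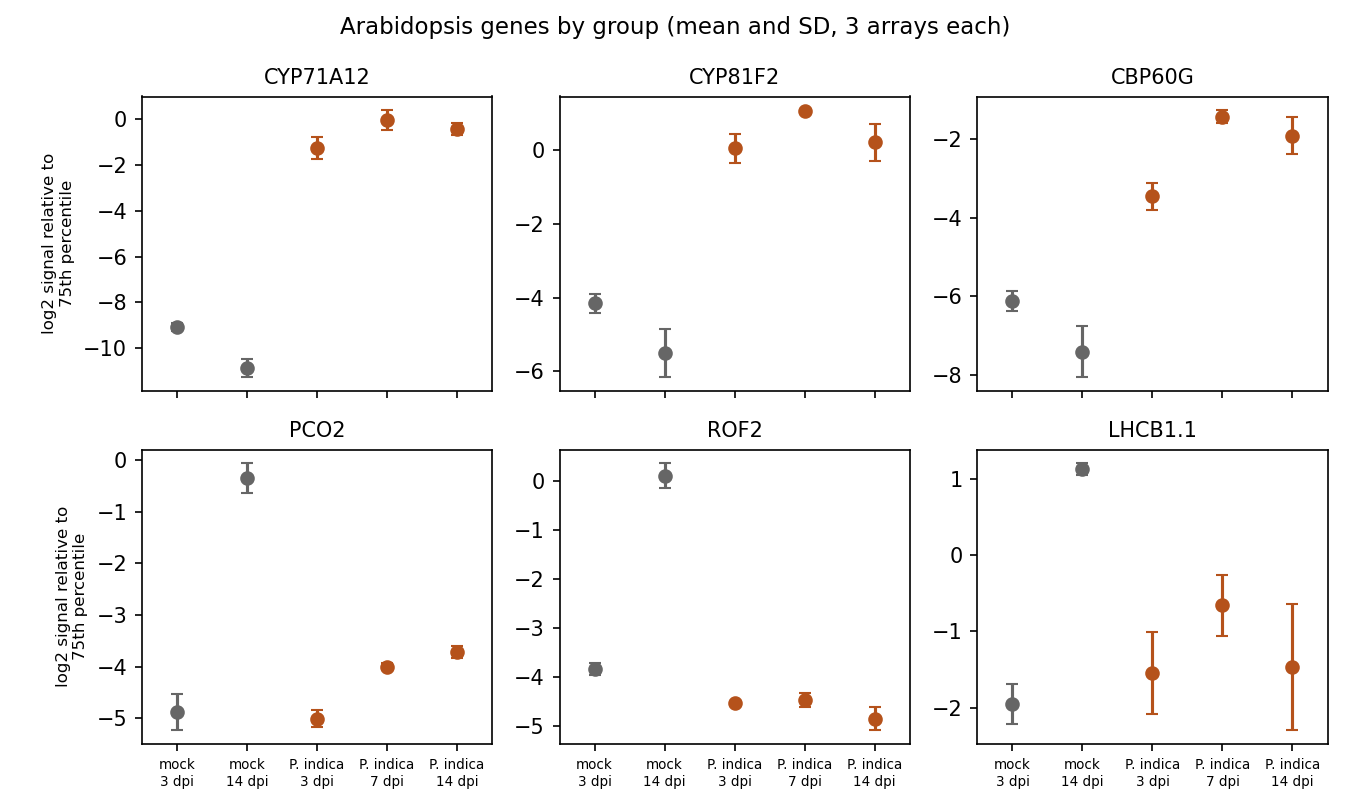
Mean log2 signal (vertical axis, bars show the SD of 3 arrays) of 6 genes in mock and P. indica roots (horizontal axis). Signals are relative to the 75th percentile of the 3840 Arabidopsis probes well above background on every array of the design. CYP71A12, CYP81F2 and CBP60G were higher with P. indica at 3 and 14 dpi, whereas PCO2, ROF2 and LHCB1.1 were highest in mock roots of 14 dpi.

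Whether the response to P. indica differed between 3 and 14 dpi was tested as the difference of the effects, which moves with the mock roots as well as with the inoculated ones. Among the 10 largest differences were CYP71B22 (AT3G26200) at 5.18 (SE 0.34, adjusted p = 1.8e-06), JRG21 (AT3G55970) at 4.87 and DIR5 at 4.63, and among the 10 most negative the clock gene GI (AT1G22770) at -5.12 (SE 0.60, adjusted p = 7.2e-05), LHCB3 (AT5G54270) at -4.93 and the ascorbate peroxidase gene APX2 (AT3G09640) at -4.62. Of 20728 genes 2088 differed (1151 with a higher and 937 with a lower effect at 14 dpi). Which direction prevails depends on the processing: a normexp correction gave 655 higher and 760 lower, and the percentile over all organisms 639 and 1937. The effect was higher at 14 dpi in 9 of 20 indole glucosinolate and camalexin genes (9 adjusted over the list alone; adjusted p = 0.00104, and adjusted p = 0.417 with an estimated correlation), such as PAD3 at 2.17 and CYP79B3 at 1.44. It was higher in 6 of 13 salicylic acid genes (6 adjusted over the list alone; adjusted p = 0.00104, and adjusted p = 0.223 with an estimated correlation), such as FMO1 at 3.69 and CBP60G at 2.83, and in 2 of 6 ER body genes (2 adjusted over the list alone; adjusted p = 0.0138, and adjusted p = 0.223 with an estimated correlation), with BGLU22 at 2.58. It was higher in 1 of 7 sugar transport genes, SWEET2 at 2.31 (1 adjusted over the list alone; adjusted p = 0.0176, and adjusted p = 0.293 with an estimated correlation), and in 1 of 7 cell division genes, CYCB1;1 at 1.62 (1 adjusted over the list alone; adjusted p = 0.00779, and adjusted p = 0.405 with an estimated correlation).

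The effect was lower at 14 dpi in 10 of 10 hypoxia genes (10 adjusted over the list alone; adjusted p = 9.53e-08, and adjusted p = 0.223 with an estimated correlation), such as PCO2 at -3.27 and LBD41 at -2.61. It was lower in 7 of 9 heat shock genes (9 adjusted over the list alone; adjusted p = 1.68e-06, and adjusted p = 0.223 with an estimated correlation), such as ROF2 at -4.27 and HSP90.1 at -3.59, and in 7 of 12 shoot photosynthesis genes (7 adjusted over the list alone; adjusted p = 0.00104, and adjusted p = 0.428 with an estimated correlation), such as LHCB1.1 at -3.00. FLS2 had a difference of 2.13. The pattern-triggered immunity (adjusted p = 0.12), jasmonate and ethylene (0.0821), phosphate (0.598), nitrogen (0.148), iron (0.0618), endodermis (0.0555), root hair (0.0894) and senescence (0.552) lists were not called.

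Mock roots of 14 and 3 dpi were compared to see how the control roots themselves changed. SRO4 was at least 23.2-fold and the ethylene response factor gene HRE2 at least 15.0-fold higher at 14 dpi. MTPA1 (AT3G61940) rose by 6.47 (SE 0.49, adjusted p = 1e-06), LHCB2.2 (AT2G05070) by 5.68 and ADH1 (AT1G77120), alcohol dehydrogenase, by 5.24 (SE 0.27, adjusted p = 1.3e-07). The senescence-associated gene SEN1 fell by 5.07 (SE 0.52, adjusted p = 9.9e-06), and the clock-related gene RVE2 and the sugar-repressed gene DIN2 were at -3.92 and -3.61. Of 20728 genes 1692 differed (876 higher, 816 lower), and after a normexp correction 1088 (689 higher, 399 lower). The percentile over all organisms gave 841 higher and 856 lower.

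All 10 hypoxia genes rose in mock roots (10 adjusted over the list alone; median 3.71, adjusted p = 1.88e-09, and adjusted p = 0.164 with an estimated correlation), among them the cysteine oxidase genes PCO2 by 4.55 and PCO1 by 3.61, and LBD41 by 3.71. Of 9 heat shock genes 6 rose (6 adjusted over the list alone; adjusted p = 0.000187, and adjusted p = 0.381 with an estimated correlation), ROF2 by 3.95 and HSP90.1 by 3.63. Of 12 shoot photosynthesis genes 7 rose (7 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.596 with an estimated correlation), LHCB1.1 by 3.08. Of 12 endodermis and suberin genes 3 rose (3 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.439 with an estimated correlation), KCS2 by 1.40, FAR4 by 1.29 and CYP86B1 by 1.19, all of suberin synthesis. Of 20 indole glucosinolate and camalexin genes 1 rose and 6 fell (1 and 6 adjusted over the list alone; adjusted p = 0.0196, and adjusted p = 0.596 with an estimated correlation), PAD3 at -1.25. Of 6 ER body genes 2 fell (2 adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.164 with an estimated correlation), BGLU22 at -2.06, and of 7 sugar transport genes 3 fell (3 adjusted over the list alone; adjusted p = 0.00299, and adjusted p = 0.198 with an estimated correlation), SWEET2 at -1.57. Of 7 cell division genes 1 fell, CYCB1;1 at -1.25 (1 adjusted over the list alone; adjusted p = 0.00299, and adjusted p = 0.413 with an estimated correlation). VSP2 rose by 2.73 and VSP1 by 1.73 in a jasmonate and ethylene list that was not called (adjusted p = 0.705). Nor were pattern-triggered immunity (0.577), salicylic acid (0.518), phosphate (0.744), nitrogen (0.119), iron (0.698), root hair (0.0695) and senescence (0.744).

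S. vermifera roots and mock roots were compared at 7 dpi, the only time with mock roots on the S. vermifera design. Per the labels the mock treatment held 0.002% Tween. For the S. vermifera roots the labels give 2 mycelium plugs per root and no Tween. Whether this difference in treatment adds to the contrast was not tested. For Arabidopsis probes the processed signal in the 3 mock files of this comparison did not follow the background-subtracted signal of the same scan. Its median offset was 1.41, 1.52 and 0.83 on the log2 scale, and the correlation across probes, which are not independent replicates, was 0.938 to 0.939. All spots of a probe held 1 value in these files and in none of the other 27. The processed values correlated at 0.976 to 0.990 with the mock arrays of 3 and 14 dpi on the P. indica design, and the background-subtracted values at 0.931 to 0.942. Each result was therefore computed also from the background-subtracted signal of every scan, and only genes that passed with both signals are said to have risen or fallen; the background-subtracted value follows the processed one.

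The P450 genes named for P. indica rose with S. vermifera as well. CYP71A12 rose by 9.48 (SE 0.19, adjusted p = 1.1e-08) from the processed and by 6.25 from the background-subtracted signal, CYP82C2 by 9.29 and 6.77, CYP82C3 by 9.00 and 6.73, and CYP82C4 by 8.68 and 6.66. NAC042 rose by 5.71 and 5.00. AZI1 fell, at -5.68 (SE 0.75, adjusted p = 0.0003) and -5.14, and so did EARLI1, at -4.65 and -4.54. Of 19801 genes tested, 2844 differed with the processed signal (1700 higher, 1144 lower) and 2093 with the background-subtracted signal (1218 higher, 875 lower). With the percentile over all organisms the lower genes prevailed (1305 higher, 1717 lower). Both signals called 739 genes higher and 464 lower, 42.3% of the first list, and 40 genes in opposite directions.

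Of 20 indole glucosinolate and camalexin genes 13 were higher with the processed signal (13 adjusted over the list alone; adjusted p = 8.31e-11, and adjusted p = 0.131 with an estimated correlation) and 12 with the background-subtracted one (adjusted p = 1.86e-12), 12 with both, CYP81F2 by 3.98 and 4.59. Of 20 pattern-triggered immunity genes 12 were higher with each signal but 8 with both (12 adjusted over the list alone; adjusted p = 3.15e-06 and 1.43e-09, and the first had adjusted p = 0.131 with an estimated correlation), PER4 by 3.17 and 3.20, WRKY33 by 1.67 and 1.69, and PROPEP3 by 1.58 and 3.35. Of 12 salicylic acid genes 6 and 7 were higher, 6 with both (6 adjusted over the list alone; adjusted p = 0.000768 and 3e-07, and the first had adjusted p = 0.138 with an estimated correlation), CBP60G by 4.28 and 4.98. Of 16 jasmonate and ethylene genes 9 and 8 were higher, 7 with both (10 adjusted over the list alone; adjusted p = 3.38e-05 and 2.33e-06, and the first had adjusted p = 0.0831 with an estimated correlation), PR4 by 1.62 and 1.87, PR3 by 1.51 and 1.83, and JAZ1 by 1.62 and 1.2. With the background-subtracted signal these 4 lists were also called with an estimated correlation (adjusted p = 0.0467, 0.0309, 0.0309 and 0.0177).

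Of 7 root hair genes 5 were lower with the processed and 7 with the background-subtracted signal, 5 with both (5 adjusted over the list alone; adjusted p = 0.0169 and 0.000367, and 0.436 and 0.257 with an estimated correlation). EXPA7 was at -2.39 and -1.73, PRP3 at -1.63 and -2.49, EXPA18 at -1.42 and -1.86, and RSL4, a regulator of root hair growth, at -1.34 and -1.51. Of 9 heat shock genes 6 and 8 were lower, 6 with both (6 adjusted over the list alone; adjusted p = 0.000768 and 2.33e-06, and 0.245 and 0.12 with an estimated correlation), with HSP17.6A at -4.05 and -5.22, HSP17.4 at -3.80 and -5.76, and ROF2 at -3.67 and -3.53. No cell division gene passed, while the list was lower as a set (0 adjusted over the list alone; adjusted p = 0.0235 and 0.0153, and 0.426 and 0.257 with an estimated correlation).

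The ER body list was called with the processed signal alone (3 of 5 higher, 3 adjusted over the list alone; adjusted p = 0.0169, and adjusted p = 0.282 with an estimated correlation) and not with the background-subtracted one (0 of 5; adjusted p = 0.06), where PYK10 went from 1.14 to 0.21. The hypoxia list changed sign, from a median of -0.82 (2 of 10 lower, 2 adjusted over the list alone; adjusted p = 0.0913) to 1.07 (6 of 10 higher; adjusted p = 0.00138, and 0.257 with an estimated correlation), with ADH1 at -2.92 and 2.06 and PCO2 at -1.66 and 0.74, so no direction is given for it. Sugar transport was called with the background-subtracted signal alone (adjusted p = 0.0913 and 0.0165, the latter 0.257 with an estimated correlation). With neither signal were the lists of phosphate (4 higher and 2 lower of 16, and 0 and 0 with the background-subtracted signal; adjusted p = 0.132 and 0.239), nitrogen (4 and 1 of 15 higher; 0.54 and 0.848), iron (4 higher and 4 lower of 16, and 4 and 0; 0.153 and 0.0502), endodermis (1 and 0 of 12 higher; 0.937 and 0.159), senescence (2 and 1 of 4 higher; 0.421 and 0.146) and shoot photosynthesis (3 and 2 of 12 higher; 0.0913 and 0.0736) called. With both signals 0 phosphate, 1 nitrogen, 2 iron, 0 endodermis, 1 senescence and 2 photosynthesis genes were higher. The counts adjusted over the list alone with the processed signal were the same except for photosynthesis, with 2. ASN1 rose by 1.37 and 1.92, and the photosynthesis gene GAPA by 2.65 and 2.44.

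**Figure D4:**
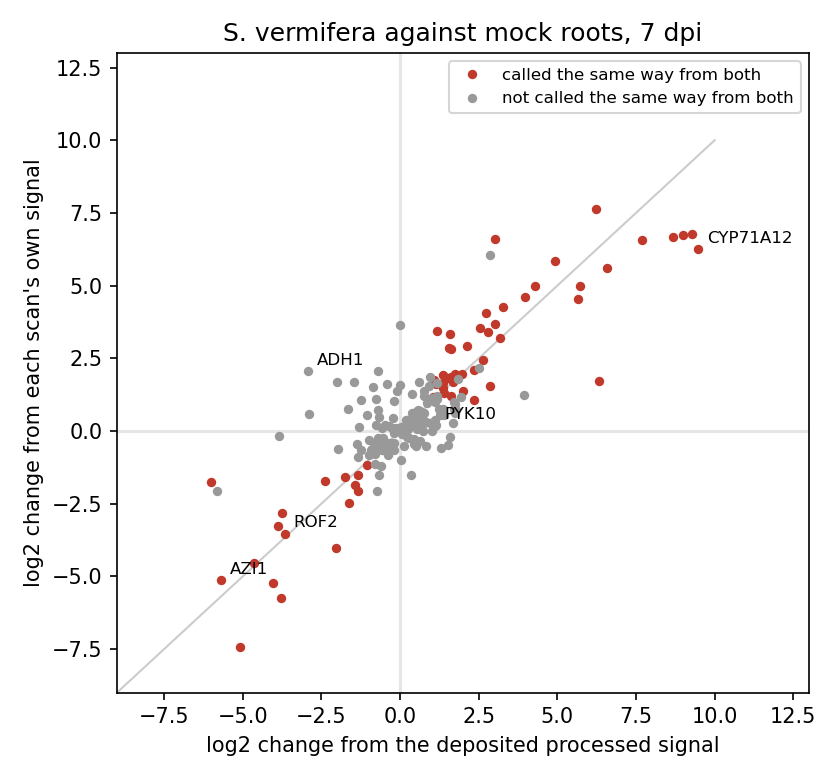
Log2 change of Arabidopsis list genes and named genes in S. vermifera against mock roots at 7 dpi, from the deposited processed signal (horizontal axis) and from the background-subtracted signal of each scan (vertical axis); each point is a gene, red where both signals called it the same way, and the line marks equal values. CYP71A12 was at 9.48 and 6.25, whereas ADH1 went from -2.92 to 2.06.

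The overlap of the plant responses to the 2 fungi was counted over 19545 genes tested on both designs. At 3 dpi with P. indica, 464 higher genes were also higher with S. vermifera at 7 dpi (58.2 from independent lists) and 155 lower genes also lower (18.0), and 13 and 21 went in opposite directions. At 14 dpi with P. indica, 701 higher genes (111) and 290 lower genes (54.8) were shared, and 36 and 46 went in opposite directions. With the background-subtracted signal for S. vermifera the shared counts were 332 and 56 at 3 dpi (43.8 and 13.5 from independent lists) and 613 and 235 at 14 dpi (83.7 and 41.3). The processed 7 dpi mock values resemble the mock arrays that are the controls of P. indica, so the lists from the processed signal may share their controls, and the numbers from independent lists are then too low. The fungi differ in design and time as well as in species, so a difference between them was not tested.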

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

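The test of the difference between the effects at 3 and 14 dpi and the counts of other splits were planned, whereas the tests of shoot tissue, slides, single arrays, the processed mock signal and shuffled residuals were chosen only after the results were seen. By the test of the difference of the effects, P. indica against mock differed between 3 and 14 dpi in 2088 Arabidopsis genes. By the same test 8 gene lists differed: indole glucosinolate and camalexin (adjusted p = 0.00104), ER body (0.0138), salicylic acid (0.00104), sugar transport (0.0176) and cell division (0.00779) with a higher effect at 14 dpi, and hypoxia (9.53e-08), heat shock (1.68e-06) and shoot photosynthesis (0.00104) with a lower one. None of these 8 was called with an estimated correlation, where the adjusted p ranged from 0.223 to 0.428. The difference moves with the mock roots too. Relative to mock roots of 3 dpi, the ER body, sugar transport and cell division medians were 0.43, 0.04 and -0.49 in P. indica roots of 3 dpi. They were 0.41, -0.03 and -0.44 in those of 14 dpi, and -0.64, -0.59 and -0.59 in mock roots of 14 dpi. The salicylic acid median was -0.01, 1.37 and -0.04 in the same groups, and the hypoxia median 0.30, 1.35 and 3.71. Among single genes the log2 difference of the effects was 5.18 for CYP71B22, 4.87 for JRG21, 4.63 for DIR5, 3.69 for FMO1, 2.83 for CBP60G, 2.58 for BGLU22, 2.31 for SWEET2, 2.17 for PAD3, 2.13 for FLS2, 1.62 for CYCB1;1 and 1.44 for CYP79B3. It was -5.12 for GI, -4.93 for LHCB3, -4.62 for APX2, -4.27 for ROF2, -3.59 for HSP90.1, -3.27 for PCO2, -3.00 for LHCB1.1 and -2.61 for LBD41. On the S. vermifera design, 7 of 472 probes named by a genome position, which no comparison used, were above background on all arrays of the fungus alone and not on all mock arrays (median log2 signal 7.81 against 4.06).

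Hypoxia genes were higher in mock roots at 14 than at 3 dpi, all 10 of them, with a median of 3.71. The shoot photosynthesis list was higher as well (7 of 12 genes rose, adjusted p = 0.0107, and 0.596 with an estimated correlation), and 46 photosynthesis genes had a median of 1.2, with LHCB2.2 at 5.68 and LHCB1.1 at 3.08. Shoot tissue in the 14 dpi mock samples as the source of the hypoxia change would bring all its abundant transcripts, yet 3 of these 46 genes rose by the hypoxia median or more. The 4 RBCS genes tested, of the most abundant leaf transcripts, were between -0.51 and 0.54 and no more than 2.42 with 2 SE added, and no scaling put one above 0.54. This argues against shoot tissue as the source of the hypoxia change, while a smaller share of it, and the cause of the rise in light-harvesting genes, stay open. The 6 mock arrays lie on 1 slide, which argues against a difference between slides, and with each array left out the median stayed at 3.49 or more, which argues against a single array. The age of the plants differs by design, and how the plates or the harvest differed between these groups was not tested. The cause of this change stays open, and it bears on P. indica against mock at 14 dpi, where the same genes were lower.

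Genes differed between P. indica and mock roots at 3 and 14 dpi, whose arrays lie on different slides that were extracted with different protocols. With the slide as a block, 75.3% of the genes called higher and 72.2% of those called lower at 14 dpi were called the same way, and 65% and 64.3% without P. indica 7 dpi replicate 1, whose signal departs from its own scan. At 3 dpi the shares were 24.6% and 6.8%, and 2.9% and 1% without that replicate, with medians of 1.15 against 1.45 for higher and -0.95 against -1.32 for lower genes. By the block alone slides would stay open as a cause at 3 dpi, so a further test was taken up after the block was seen. A difference between slides of this design would not recur with S. vermifera on the other design, where both groups lie on the same 3 slides. From the background-subtracted signal there, 332 of 733 genes higher at 3 dpi were higher and 56 of 307 lower ones lower. Independent lists would share 43.8 and 13.5. At 14 dpi 613 of 1401 and 235 of 937 recurred (83.7 and 41.3 from independent lists). These are the called genes tested on both designs, out of 801, 487, 1585 and 1203 called. The recurrence argues against slides as the whole cause of each of the 4 sets, and does not cover genes that were not tested there. Slides stay open as a cause of a part of the calls at 3 dpi. Within the slide of the mock arrays, a single P. indica array of 7 dpi set against mock roots of the other time gave medians of 1.54 and -0.65 for the genes of 3 dpi, and 0.92 and -0.38 for those of 14 dpi (1.59 and -1.48 in the contrast); 1 array excludes nothing. With the block at 3 dpi CBP60G went from 2.66 (adjusted p = 6.4e-05) to 2.38 (0.062) and WRKY33 from 1.57 (0.00014) to 1.36 (0.11). In these genes the changes in size are small beside the wider error of a block resting on 3 arrays. BNQ3 and SARD1 shrank more, from -2.80 to -1.93 and from 2.30 to 1.63, while FLS2, VSP2 and DIR1 grew in size. The different number of plants pooled and fungal RNA on plant probes also stay open and were not tested.

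The processed mock signal that does not follow its own scan is a candidate cause of part of the differences between S. vermifera and mock roots at 7 dpi. Of the called genes 42.3% were called the same way from the background-subtracted signal, and the hypoxia median turned from -0.82 to 1.07, both of which the explanation predicts. For the indole glucosinolate and camalexin list it fails, since this list was higher from the background-subtracted signal as well (adjusted p = 1.86e-12). Which of the signals is nearer to the RNA of these samples was not tested.

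Splits of the same arrays into other groups were counted for each contrast of 3 against 3 arrays, which has 10 splits and so cannot give a share under 0.05. In each, 1 split, the real one, gave as many genes. The real and highest other counts were 1542 and 0 for S. vermifera at 3 dpi against alone, 1504 and 0 at 14 dpi, and 706 and 1 at 14 against 3 dpi in roots. For P. indica they were 1026 and 0 at 7 against 3 dpi, 1624 and 0 at 14 against 3 dpi, and 489 and 0 at 14 against 7 dpi. For Arabidopsis with P. indica they were 1288 and 1 at 3 dpi and 2788 and 0 at 14 dpi, and for mock roots 1692 and 5. For the difference of the effects, other splits put the effects of fungus and time into the contrast and its error, which is a structure of the samples: 1 of them gave 4509 genes against the real 2088, and they decide nothing. Residuals of a fit without a difference of effects were therefore shuffled among the arrays. As many genes came in 3 of 100 such splits, the real one included, with 2162 as the highest other. This share of 0.03 is under 0.05. The test was chosen only after the planned splits decided nothing, so chance is not excluded by it.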

How the results depend on the processing

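The background-subtracted signal, the unmerged 7 dpi arrays, the slide block for lists and leaving out P. indica 7 dpi replicate 1 elsewhere or with a block were chosen only after the results were seen; the other alternatives were planned. S. vermifera contrasts are named here by their times in the order 3, 7 and 14 dpi against alone, then 7 against 3, 14 against 3 and 14 against 7 dpi, and P. indica contrasts in that last order. Where no reason is given for a count over 1.5 times or under 1/1.5 of the reported one, the cause was not tested. Of 157 values of named genes, none lost its call or direction with the brightest probe, cross-lit probes kept, eBayes with trend and robust settings, no dim filter or a replicate block. Single arrays left out changed the calls of 5, all of P. indica genes: PIIN_02121 at 14 against 3 and 14 against 7 dpi, PIIN_02023 and PIIN_08944 at 7 against 3 dpi, and PIIN_01005 at 14 against 7 dpi. The slide block ended 14 (21 without P. indica 7 dpi replicate 1), normexp 6, the percentile over all organisms 4, quantile normalization 3 and the series matrix 1. No fold minimum made calls of 7 more.

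Without a fold minimum, fewer conditions apply and counts rose by construction: to 5853, 5099, 5323, 2548, 3539 and 3179 for S. vermifera, 3478, 4476 and 2129 for P. indica, and for Arabidopsis 8338 and 12096 with P. indica at 3 and 14 dpi, 7343 for the difference of effects, 9475 for mock roots and 10060 with S. vermifera. Overlaps between fungi were then 2272 higher and 2201 lower at 3 dpi, and 2588 and 2298 at 14 dpi, and those between S. vermifera times 1250 and 1393. With no dim filter more genes were tested, and counts were 3638, 4788, 4060, 3387 and 1470 for S. vermifera (14 against 3 dpi excepted), 3508, 4089 and 1909 for P. indica, and 4719 for Arabidopsis with S. vermifera. The strict filter tested fewer genes and gave 906, 635, 715, 132, 312 and 186 for S. vermifera and 79, 720 and 32 for P. indica. In P. indica contrasts with 7 dpi the strict filter leaves 598 or 758 genes, and 5016 at 14 against 3 dpi. It needs a probe well above background on all compared arrays. Replicate 1 of 7 dpi had 1057 such fungal probes, against 8164 and 7895 on replicates 2 and 3, so that array limits the genes left.

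The percentile over all organisms carries the share of fungal RNA into each fungal gene. It gave 11337, 11338, 11333, 4353 and 2971 for S. vermifera (14 against 3 dpi excepted), with medians of all genes of -5.56, -6.41 and -5.68 against alone, and 6197, 7676 and 2426 for P. indica, with medians of 1.39, 2.24 and 0.81. Under it Sebve1_12373 turned to -0.02 at 7 dpi, and Arabidopsis with P. indica at 14 dpi had 912 higher and 3168 lower genes at a median of -0.42. Normexp gave 5392 and 2941 at 7 and 14 dpi against alone, 2914, 195 and 1458 between S. vermifera times, 2162 and 188 for P. indica at 7 against 3 and 14 against 7 dpi, 728 for P. indica against mock at 3 dpi, 1088 for mock roots and 1186 for S. vermifera against mock, where ADH1 turned to 1.77 and PCO2 to 0.65. Its medians of all fungal genes were 0.89 at 7 dpi against alone and -0.60 for P. indica at 7 against 3 dpi. Only the compared groups gave 252 and 411 for S. vermifera at 7 against 3 and 14 against 7 dpi and 579 for P. indica at 7 against 3 dpi, with fewer genes tested. Quantile normalization gave 296 for P. indica at 14 against 7 dpi, and the slide block 257 for P. indica against mock at 3 dpi, and 38 without 7 dpi replicate 1.

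The direction split also moved where totals did not. At 7 dpi against alone the series matrix gave 552 higher and 1743 lower S. vermifera genes. At 14 against 3 dpi it gave 345 and 400 and the percentile over all organisms 309 and 414, and at 14 against 7 dpi the series matrix gave 725 and 266 and quantile normalization 617 and 261. For P. indica, cross-lit probes kept gave 594 and 689 at 7 against 3 dpi and 1248 and 661 at 14 against 3 dpi, quantile normalization 882 and 297 at 7 against 3 dpi, and the other probe set 235 and 121 at 14 against 7 dpi. The difference of effects had 655 higher and 760 lower with normexp, 639 and 1937 with the percentile over all organisms, and 777 and 807 with the strict filter.

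With an estimated correlation the number of called lists went from 4, 10, 8, 8 and 8 (P. indica at 3 and 14 dpi, difference of effects, mock roots, S. vermifera) to 0 in each; fry, which does not compare a list with other genes, gave 8 at 3 dpi and 13 with S. vermifera. With the background-subtracted signal ADH1 turned to 2.06, PCO2 to 0.74 and the hypoxia list to higher (adjusted p = 0.00138, and 0.257 with an estimated correlation), and the overlap of lower genes at 3 dpi was 56. The fungal minus plant difference from mock, taken at the 75th percentile, was 6.37, 5.26 and 6.24 for S. vermifera and 4.25 and 6.32 for P. indica at 3 and 14 dpi, and 3.17, 2.11 and 3.04 for S. vermifera with the background-subtracted plant signal. That signal gave 2.53 for P. indica at 7 against 3 dpi and 0.14 at 14 against 7 dpi, and 1.63 and 1.04 without 7 dpi replicate 1. All kept their sign.

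With each array left out in turn, counts ranged over 1456 to 1620, 1484 to 1658, 1420 to 1618, 395 to 800, 672 to 735 and 547 to 847 for S. vermifera, and 990 to 1072, 1528 to 1694 and 217 to 635 for P. indica. The lowest at 7 against 3 dpi was without S. vermifera 7 dpi replicate 3, which leaves 1 averaged sample at 7 dpi, and the 217 without P. indica 7 dpi replicate 1 (155 higher, 62 lower). For Arabidopsis they ranged over 1159 to 1464 and 2768 to 2907 with P. indica, 1906 to 2235 for the difference, 1622 to 1818 for mock roots and 2705 to 2864 with S. vermifera. The fungal signal differences ranged over -1.25 to -0.94, -0.33 to -0.04 and 0.80 to 0.96 between S. vermifera times, 4.26 to 4.64, 3.20 to 3.56 and 4.12 to 4.48 against mock, 1.38 to 1.75, 2.38 to 2.91 and 0.81 to 1.34 between P. indica times, and 2.14 to 2.61 and 4.31 to 4.84 against mock.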

Other observations

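Plant genes of P. indica roots at 7 dpi and of S. vermifera roots at 3 and 14 dpi were not tested, and their values are described here beside those of tested groups. The P. indica values of 7 dpi include replicate 1, with 15.7% of plant probes well above background. P. indica roots of 7 dpi have no mock roots of that time on their array design, so their plant genes are described relative to mock roots of 3 dpi. On that scale the hypoxia genes had a median of 0.30 in P. indica roots at 3 dpi, 1.36 at 7 dpi and 1.35 at 14 dpi, and the heat shock genes 0.16, -0.67 and -0.53. Log2 signals on the P. indica design are relative to the 75th percentile of the 3840 Arabidopsis probes well above background on every array. CYP71A12 was at -9.06 ± 0.18 (SD, n = 3) in mock roots of 3 dpi, -1.27 ± 0.49 in P. indica roots at 3 dpi, -0.03 ± 0.43 at 7 dpi and -0.43 ± 0.27 at 14 dpi. CYP81F2 was at -4.16 ± 0.25, 0.04 ± 0.39, 1.04 ± 0.04 and 0.20 ± 0.51 in the same groups, and CBP60G at -6.12 ± 0.26, -3.46 ± 0.35, -1.43 ± 0.17 and -1.92 ± 0.47.

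In S. vermifera roots, without mock roots of 3 and 14 dpi, CYP71A12 was at 2.31 ± 0.20 (SD, n = 3) at 3 dpi, 2.57 ± 0.31 (n = 2) at 7 dpi and 1.2 ± 0.28 (n = 3) at 14 dpi on the scale of that design. LBD41 was at 1.76 ± 0.20, 1.07 ± 0.05 and 2.68 ± 0.57, and ROF2 at 0.51 ± 0.40, -2.04 ± 0.04 and -2.80 ± 0.15.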
